A study of Homo sapiens with 6 samples.

How the data were processed

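RNA-seq was made from 6 libraries of PLC/PRF/5, a human hepatoma cell line. Of these, 3 came from cells given a control vector and 3 from cells given a plasmid that expresses ARD1, all collected 48 hours after transfection. Per the labels' protocols, RNA was extracted with Trizol, ribosomal RNA was depleted, and a directional library kit was used. Per the submitters' processing notes, cutadapt 4.6 and STAR 2.7.11b were used with the GRCh38 build. The counting program, its strand setting and the annotation release are not given in the sources used here.

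The deposited table holds raw, whole-number counts per Ensembl gene for each library, without normalization. It lists 25071 genes, each with at least 2 counts over the 6 libraries, so genes with fewer counts appear to have been left out by the authors before deposit, as read from the values. Every entry had a gene identifier. Of the identifiers, 25052 matched a symbol in the names table used here and 19 did not, and 23129 were found in GENCODE 29, which gave coordinates, GC content and transcript length. A library held between 21857327 and 25011357 counts. At this depth 3 counts correspond to 0.120 to 0.137 CPM, counts scaled by library size. Without molecular identifiers, counts are not independent molecules, so intervals and floors cover counting error only.

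Groups and replicate numbers were taken from the sample titles. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Genes were kept by edgeR's filterByExpr, which left 15816 and removed 9255, and library sizes were scaled by TMM. The groups were compared with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) over all 6 libraries, with Benjamini-Hochberg adjusted p under 0.05 as the threshold and no further covariate. CPM values are TMM-normalised and given as mean ± SD with n = 3 per group, and standard errors of log2 fold changes were derived from the F statistic. The design has 1 comparison, ARD1 plasmid against control vector, and fold changes are ARD1 plasmid over control vector.

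Before the data were examined, 32 gene lists, 17 core genes, the alternatives below and a rule for named genes were fixed. Lists with at least 5 tested genes were compared with all other genes by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. The rule named NAA10, the core genes, and the 12 largest rises and 12 largest falls among genes with a symbol, an adjusted p past the threshold, at least 1 CPM in the higher group and no overlap between the groups' libraries. It also named the 4 members with the smallest p of each list past camera, and up to 2 changed members of each other list. Some genes that the rule names are not reported here. Genes named outside the rule are said to be chosen after their values were seen. Where a group had 0 counts, the fold is a lower bound against 3 counts over that group. Where a group had 1 to 3 counts, the ratio has an exact conditional 95% interval.

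The edgeR, GC offset and camera steps were tested on simulated data for this comparison, with counts drawn for the 15816 genes and 200 of them changed. Of the genes changed 1.5-fold, 2-fold and 4-fold, 82.1%, 95.5% and 100% were recovered, and 8.87% of the 203 calls were unchanged genes. With GC and length offsets 92.5% of the 200 changed genes were recovered. No GC or length trend was simulated, so whether the offsets remove such a trend was not tested. camera called 0 of 20 unchanged lists. Each gene was drawn independently of the others, so the simulation cannot show how camera behaves when genes of a list are correlated. The changed genes were taken from well-counted genes and were a far smaller share than in the data. The rates may therefore not carry over.

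Alternatives fixed beforehand were RLE and upper-quartile scaling, library sizes without NAA10, DESeq2 1.42.0, limma-voom, no filter beyond the table's own, a filter of 1 CPM in 3 libraries, the replicate number as a block, leaving out each library in turn, and a minimum absolute log2 fold change of 1. For lists they were camera with an estimated correlation, fry, RLE scaling, the stricter filter, the block and each left-out library. Alternatives on pseudocounts applied to normalized values and were not run on counts. Loess offsets for GC content and transcript length per library, library totals without scaling factors, thinning to equal depth and leaving out the 20 most abundant genes were chosen after seeing the data.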

Results

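Gene expression was measured in 6 libraries of PLC/PRF/5 hepatoma cells, 3 transfected with a control vector and 3 with a plasmid expressing ARD1. ARD1 is another name of NAA10, the catalytic subunit of the N-terminal acetyltransferase complex NatA. The study's title links ARD1 to escape from ferroptosis, an iron-dependent form of cell death driven by lipid peroxidation, through glutathione synthesis and acetylation of the poly(A)-binding protein PABPC1. The comparison therefore addresses which transcripts differed 48 hours after transfection, and whether those of glutathione synthesis were among them. The control libraries held 25011357, 22715392 and 23950310 counts and the ARD1 libraries 21857327, 24423503 and 22571780. Libraries of a group correlated at 0.989 to 0.993 in log2 CPM across genes, which are not independent replicates, and libraries of different groups at 0.926 to 0.935. Control replicate 1 stood apart from the other controls, with a chi-square per degree of freedom of 17.6 and 20.5 against them, where control replicates 2 and 3 gave 2.98 and pairs of ARD1 libraries 2.504 to 4.398. No pair of libraries differed by so little as sampling noise.

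NAA10 (ENSG00000102030), the transfected gene, was 10.1-fold higher in the ARD1 libraries. It lies on chromosome X at 153929242 to 153935223 on the minus strand (GRCh38, GENCODE 29), and 10.1% of its exon bases overlap exons of ARHGAP4 on the same strand. Its level was 35.6, 32.2 and 36.2 CPM in the control libraries and 355, 400.2 and 294 CPM in the ARD1 libraries (log2 fold change 3.34, SE 0.107, adjusted p = 3.53e-12). Counts in this gene do not separate plasmid-derived from chromosomal transcripts. NAA15, which anchors NAA10 in NatA, did not pass the test (log2 fold change 0.20, adjusted p = 0.108), and its direction depended on the setting, at 0.46 with library totals alone (adjusted p = 0.00407, range over its alternatives 0.00407 to 0.411) and -0.13 with GC and length trends removed (adjusted p = 0.0537).

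Transcripts of cystine uptake and of the first step of glutathione synthesis were higher in the ARD1 libraries. SLC7A11, the cystine/glutamate exchanger, rose from 174 ± 25.6 to 576 ± 37.8 CPM (SD, n = 3; log2 fold change 1.73, SE 0.0974), and its partner chain SLC3A2 from 204 ± 16.04 to 562 ± 13.5 CPM (1.47, SE 0.0732). GCLC, the catalytic subunit of glutamate-cysteine ligase, rose from 82.3 ± 5.01 to 185 ± 0.478 CPM (1.17, SE 0.0708), and the modifier subunit GCLM rose by less (0.47, SE 0.0745). GSS, which completes glutathione, did not pass the test at 60.5 ± 4.003 and 62.8 ± 1.44 CPM (0.05, adjusted p = 0.547). CHAC1, which degrades glutathione, also rose, from 4.73 ± 0.501 to 20.7 ± 1.27 CPM (2.13, SE 0.120), as did NFE2L2, which encodes the transcription factor NRF2 (1.84, SE 0.121). Of NFE2L2 exon bases, 17.6% overlap exons of AC019080.1 on the same strand. PABPC1 itself fell from 2386 ± 117 to 1878 ± 48.5 CPM (-0.35, SE 0.0681, adjusted p = 0.000423).

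Of the other ferroptosis genes fixed beforehand, 3 fell and 1 rose. GPX4, the lipid hydroperoxidase, had a log2 fold change of -0.46 (SE 0.0783), ACSL4, which activates polyunsaturated fatty acids, -0.42 (SE 0.0989), and the heme oxygenase HMOX1 -0.41 (SE 0.0819), each past the threshold. The ferritin heavy chain FTH1 rose by 0.55 (SE 0.0772). AIFM2 (-0.12), the transferrin receptor TFRC (-0.03) and the ferritin light chain FTL (-0.06) did not pass. Of the 17 core genes, the transfected NAA10 included, 12 passed the threshold over all genes tested, and 12 adjusted over the list alone. Of all tested genes 64.6% passed, so this count alone does not set the core genes apart. With library totals and no scaling factors, PABPC1 (-0.08, adjusted p = 0.209, range over its alternatives 1.32e-08 to 0.209), ACSL4 (-0.16, 0.219, range 2.40e-12 to 0.219) and HMOX1 (-0.14, 0.0920, range 9.84e-07 to 0.0920) no longer passed. With GC and length trends removed GPX4 no longer passed (-0.09, adjusted p = 0.0698, range over its alternatives 6.65e-10 to 0.0953), GCLM came to 0.14, HMOX1 to -0.14 and ACSL4 to -0.74. With trends removed and with totals, GSS (0.20 and 0.32) and FTL (0.13 and 0.21) passed as higher and TFRC passed in opposite directions (-0.24 and 0.23). PABPC1, GPX4, FTH1 and FTL have near-identical processed copies in the genome, and 62.4% of FTH1 exon bases lie opposite BEST1 exons, so their counts are uncertain to that extent.

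**Figure D1:**
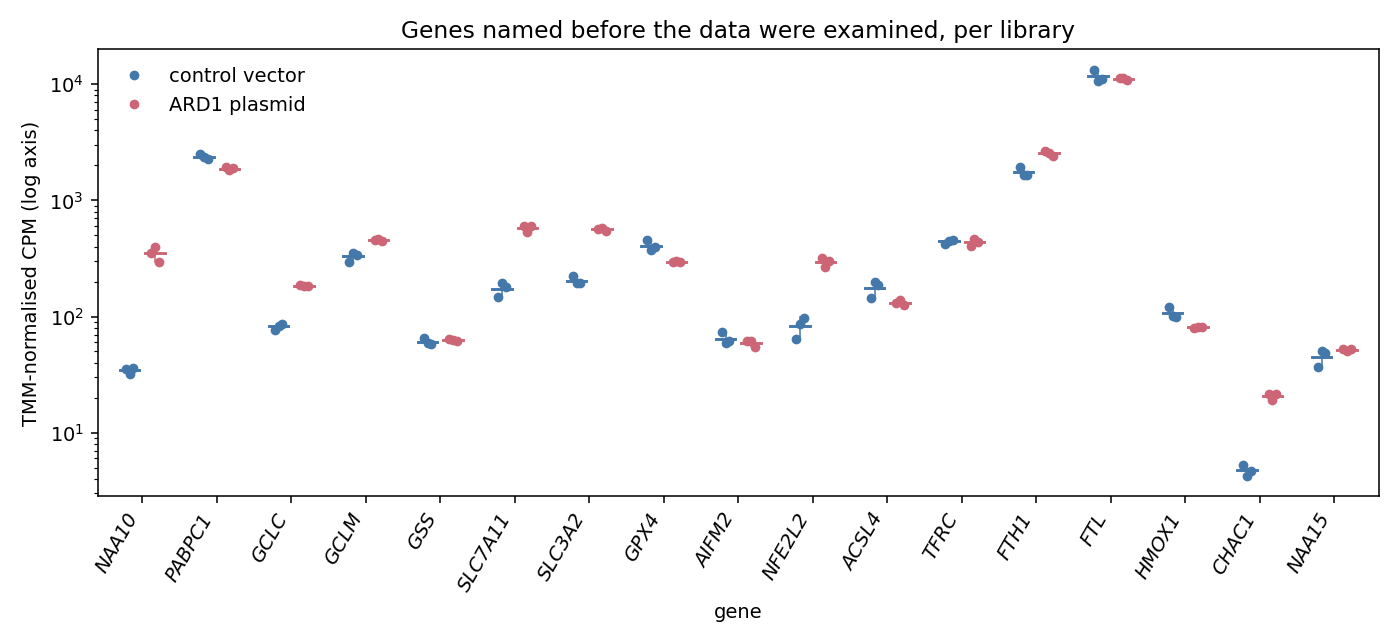
TMM-normalised CPM on a log axis for the 17 core genes (x axis), with a point per library, a horizontal line for the group mean and a vertical line for ± 1 SD (n = 3 per group). NAA10 lies between 294 and 400.2 CPM in the ARD1 libraries and between 32.2 and 36.2 CPM in the controls. The groups do not overlap for SLC7A11, SLC3A2, GCLC, GCLM, NFE2L2, CHAC1 and FTH1, which are higher in the ARD1 libraries. Nor do they for PABPC1, GPX4, ACSL4 and HMOX1, which are lower, or, narrowly, for NAA15, which did not pass the test. GSS, AIFM2, TFRC and FTL overlap.

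The difference between the groups covered much of the transcriptome. Of 15816 genes tested, 10223 (64.6%) changed in edgeR's quasi-likelihood test, 5127 higher and 5096 lower in the ARD1 libraries, and 3406 of them by an absolute log2 fold change of at least 1 (1536 higher, 1870 lower). With library totals alone the median of all genes moved from 0.03 to 0.30 on the log2 scale, and 68.6% of the changed genes were higher in place of 50.2%. Directions below are relative to the TMM scaling.

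The largest rises were in genes with almost no counts in the controls. NGFR, a neurotrophin receptor, had 0 counts in the control libraries and 5.82 ± 0.704 CPM in the ARD1 libraries, at least 127-fold higher, and SLC22A25 and ATP1B4 were at least 99.0-fold and 97.6-fold higher. LINC02485 was at least 25.4-fold higher. KLHDC7B (log2 fold change 6.18), the homeobox gene HOXB9 (5.67), LINC00656 (5.29) and ADGRF4 (4.92) rose from under 0.2 CPM. For RADIL, LARP4B-DT, VWF and CMKLR2, with 1 to 3 control counts, the ratios were 69.3 (95% interval 12.1 to 2771), 45.9 (12.4 to 384), 45.5 (12.3 to 380.4) and 38.7 (12.96 to 190.0). Of NGFR exon bases, 27.1% lie opposite exons of other genes.

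The largest falls included well-expressed genes. CDH5, the endothelial cadherin, fell from 33.1 ± 2.44 to 0.0677 ± 0.0836 CPM (log2 fold change -8.85, SE 0.264), and SOST, a secreted Wnt antagonist, from 131 ± 3.60 to 1.02 ± 0.386 CPM (-7.01, SE 0.147). The lipase LIPE (-8.02), the alcohol dehydrogenase ADH1C (-7.56) and LCNL1 (-7.00) fell to below 0.5 CPM. PLA2G3, GPR149, RPS6KA6 and ZNF366 had 0 counts in the ARD1 libraries and were at least 48.5-fold, 45.0-fold, 32.3-fold and 28.5-fold lower. KRT13 and RGS1, with 1 count left, were lower by ratios of 399 (95% interval 71.2 to 15824) and 203 (36.0 to 8071).

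Genes of the integrated stress response and targets of its transcription factor ATF4 rose. Of 41 members tested, 28 were higher and 9 lower, with a median log2 fold change of 0.67 (camera adjusted p = 9.88e-05, adjusted p = 0.368 with an estimated correlation). GDF15, a stress-induced cytokine, rose from 10.7 ± 1.24 to 119 ± 5.39 CPM (3.48, SE 0.0954), DDIT3 from 16.7 ± 1.26 to 94.1 ± 2.62 CPM (2.49, SE 0.0838), and PPP1R15A, which directs dephosphorylation of eIF2α, from 70.0 ± 4.21 to 291 ± 26.4 CPM (2.06, SE 0.0826). CTH, the enzyme that makes cysteine from cystathionine, rose from 5.66 ± 0.544 to 37.0 ± 2.80 CPM (2.71, SE 0.112). CBS, the step before CTH, fell by 1.91 on the log2 scale. Of DDIT3 exon bases, 31.6% lie opposite exons of other genes.

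Targets of p53 were also higher, with 15 of 27 higher, 5 lower and a median of 0.36 (adjusted p = 0.0315, adjusted p = 0.363 with an estimated correlation). GDF15, SESN2 (1.72) and ZMAT3 (1.28) rose and PLK2 fell (-1.38), and GDF15 and SESN2 are members of the ATF4 list as well. Without control replicate 2 this list did not pass (adjusted p = 0.0584, range over its alternatives 0.00641 to 0.363).

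Lipid synthesis genes fell together. Of 24 genes in the cholesterol synthesis list 21 fell and 0 rose, with a median of -1.45 (adjusted p = 1.64e-08, adjusted p = 0.140 with an estimated correlation). The squalene synthase FDFT1 fell from 609.7 ± 36.4 to 136 ± 5.63 CPM (-2.17, SE 0.0730) and the lanosterol synthase LSS from 144 ± 9.88 to 34.1 ± 0.409 CPM (-2.08, SE 0.0769). In fatty acid synthesis and desaturation 20 of 26 genes fell and 4 rose, with a median of -1.12 (adjusted p = 5.87e-05, adjusted p = 0.363 with an estimated correlation). The desaturases FADS2 (1617 ± 197 to 66.9 ± 2.83 CPM, -4.59) and SCD (3380.3 ± 288 to 536 ± 5.23 CPM, -2.66) and the fatty acid synthase FASN (-2.88) fell, as did SREBF1 (-2.32), a transcription factor gene of this pathway.

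Hypoxia-inducible genes fell in 22 of 33 cases and rose in 3, with a median of -0.68 (adjusted p = 0.000307, adjusted p = 0.368 with an estimated correlation). The carbonic anhydrase CA9 went from 133 ± 11.7 to 5.60 ± 0.359 CPM (-4.57, SE 0.101), and the glycolytic enzymes ALDOC (-3.34) and PGK1 (-2.03) and the stress protein NDRG1 (-1.87) fell too. Exons of ARHGEF39 lie opposite 38.5% of CA9 exon bases. Of 18 Wnt and beta-catenin targets 14 fell and 1 rose, with a median of -0.77 (adjusted p = 9.88e-05, adjusted p = 0.368 with an estimated correlation). These included LGR5 (-5.01), the Wnt inhibitors NOTUM (-4.70) and NKD1 (-2.47), and BMP4 (-1.41).

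Hepatocyte genes were lower in 15 of 26 cases and higher in 7, with a median of -0.64 (adjusted p = 0.0315, adjusted p = 0.481 with an estimated correlation). Albumin (ALB) fell from 315 ± 6.37 to 36.3 ± 3.89 CPM (-3.12, SE 0.0847), transferrin (TF) from 161 ± 15.3 to 17.3 ± 0.825 CPM (-3.22, SE 0.0901), and ITIH2 (-1.24) and complement C3 (-1.55) by less. This list did not pass with the filter of 1 CPM in 3 libraries (adjusted p = 0.0613) or with GC and length trends removed (adjusted p = 0.226, range over its alternatives 0.00843 to 0.481).

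DNA replication genes fell in 24 of 34 cases and rose in 1, with a median of -0.48 (adjusted p = 9.88e-05, adjusted p = 0.140 with an estimated correlation). The helicase subunits MCM3 (-1.62) and MCM5 (-1.45), the cell cycle transcription factor E2F1 (-1.64) and UHRF1, a factor in maintenance of DNA methylation (-1.17), were examples. Genes of G2/M and mitosis did not pass as a list, with 11 of 30 lower, among them AURKB (-0.84) and KIF20A (-0.55), and 4 higher (adjusted p = 0.394).

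Cytosolic ribosomal protein and oxidative phosphorylation transcripts were lower. The size of the fall rests on the scaling. Of 59 cytosolic ribosomal protein genes 53 fell and 1 rose, with a median of -0.51 (-0.24 with library totals alone, main adjusted p = 1.11e-09, adjusted p = 0.368 with an estimated correlation). RPL27 (-1.01), RPL3 (-0.91) and RPS3 (947 ± 91.0 to 473 ± 12.4 CPM) were examples. Of 13 mitochondrially encoded transcripts 11 fell and 0 rose, with a median of -0.67 (-0.40 with library totals alone, main adjusted p = 0.000307, adjusted p = 0.526 with an estimated correlation), led by MT-ATP6 (-0.97), MT-ATP8 (-0.90), MT-CYB (-0.84) and MT-CO3 (-0.89). All genes with a symbol starting with MT-, these 13 included, took 7.59% to 7.81% of the counts of a control library. They took 5.62% to 6.28% of those of an ARD1 library. Of 43 nuclear genes of oxidative phosphorylation 26 fell and 6 rose, with a median of -0.34 (adjusted p = 0.00997, adjusted p = 0.541 with an estimated correlation), UQCRC2 (-1.46), NDUFV1 (-1.08), COX7A2 (-0.97) and COX6B1 (-0.99) among them. With library totals alone the median of this last list was -0.08 and it did not pass (adjusted p = 0.0696, range over its alternatives 0.00259 to 0.541). Ribosomal protein genes have many processed copies, and their counts are uncertain to that extent.

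**Figure D2:**
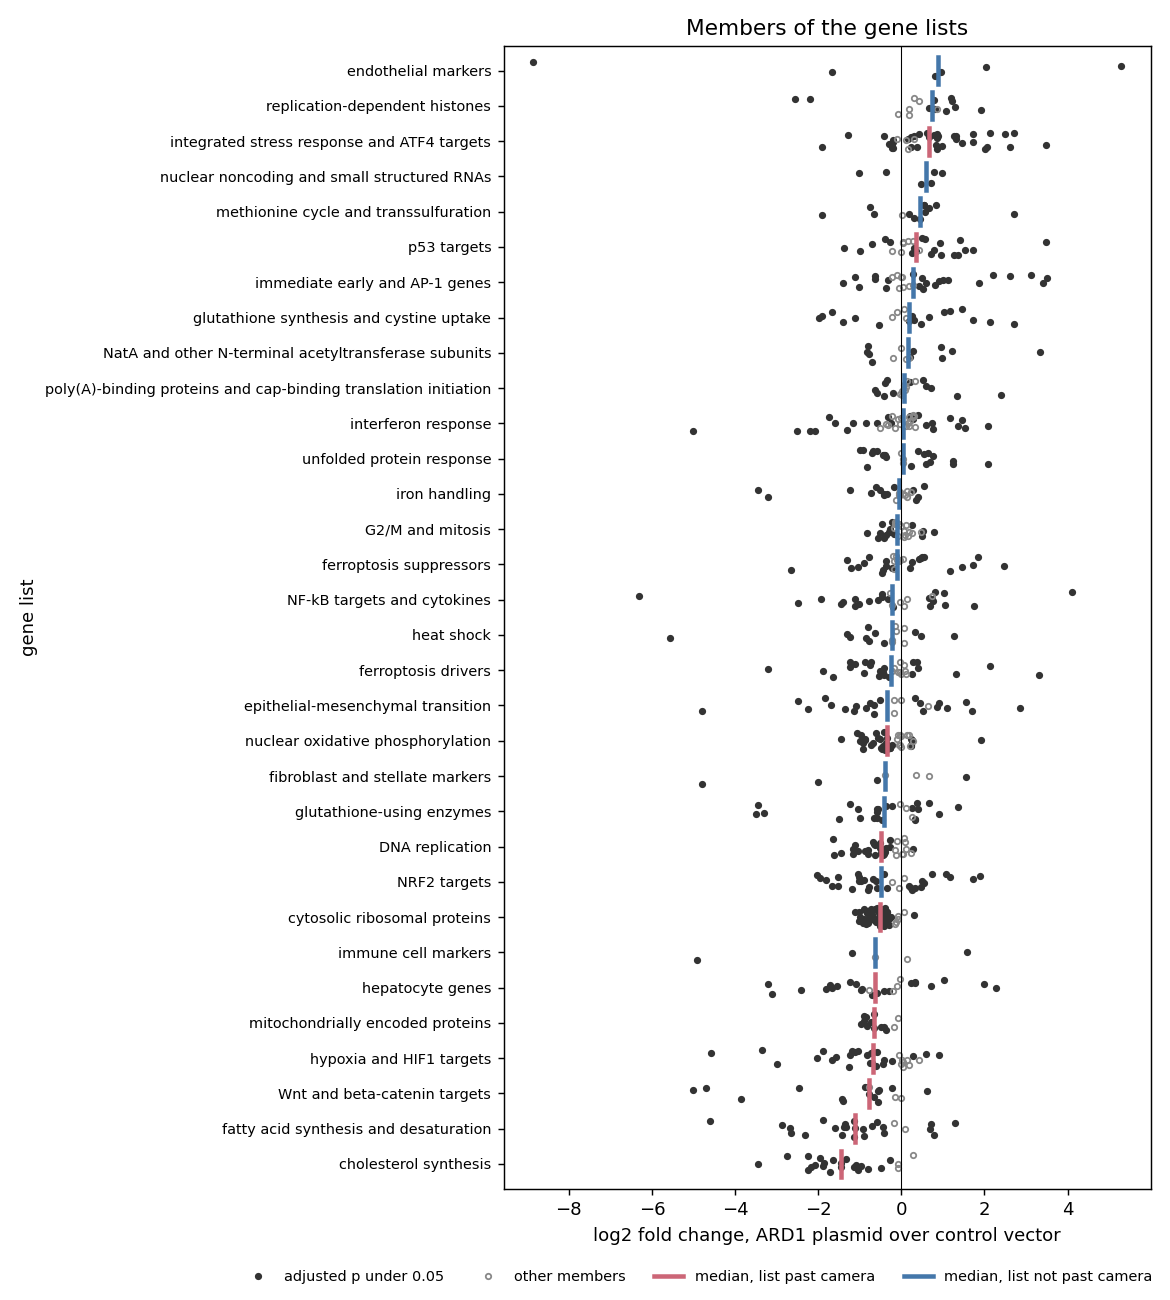
Log2 fold change of ARD1 plasmid over control vector (x axis) for the tested members of the 32 gene lists (y axis), with filled points for members with an adjusted p under 0.05 and open points for the others, and a bar at each list's median. Cholesterol synthesis has the lowest median (-1.45), and the lists past camera are 2 higher and 9 lower.

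The remaining 21 lists did not pass camera. In glutathione synthesis and cystine uptake 11 of 21 genes were higher and 6 lower, among them the 5-oxoprolinase OPLAH (-1.97) (median 0.18, adjusted p = 0.380). The methionine cycle and transsulfuration list had 9 of 13 higher and 3 lower (adjusted p = 0.123). Glutathione-using enzymes had 15 of 26 lower and 8 higher (adjusted p = 0.0963), with the transferase GSTA1 at -3.49 and the peroxidase GPX2 at -3.44. Ferroptosis suppressors had 11 of 30 higher and 11 lower (adjusted p = 0.790), and drivers 7 of 32 higher and 16 lower (adjusted p = 0.0773), including FADS1 (-1.90). Of 24 iron-handling genes 10 were lower, led by TF and ceruloplasmin (CP, -3.45), and 4 higher (adjusted p = 0.229). NRF2 targets had 19 of 34 lower and 12 higher (median -0.49, adjusted p = 0.0895), with the aldo-keto reductases AKR1B10 (-1.96) and AKR1C2 (-1.66) among those that fell. With library totals alone the NRF2 list passed (adjusted p = 0.0454, range over its alternatives 0.0454 to 0.503).

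N-terminal acetyltransferase subunits, a list that holds NAA10 itself, had 6 of 14 higher, NAA30 (0.96) among them, and 4 lower (adjusted p = 0.718). Poly(A)-binding and cap-binding factors had 6 of 20 higher and 6 lower (adjusted p = 0.595), with PABPC1L at 2.40 and EIF4B at -0.64. The unfolded protein response was split, with 10 of 23 higher, including the sensors ERN1 (2.08) and ATF6 (1.25), and 10 lower (adjusted p = 0.833). Heat shock genes had 8 of 17 lower, CRYAB (-5.57) and HSPA1A (-1.24) among them, and 3 higher (adjusted p = 0.0773), and passed without control replicate 1 (adjusted p = 0.0457, range over its alternatives 0.0457 to 0.368). Immediate early genes had 15 of 30 higher, with EGR1 at 3.40 and ATF3 at 2.63, and 7 lower (adjusted p = 0.0963). Interferon response genes had 11 of 40 higher and 12 lower (adjusted p = 0.736), with IFITM1 (-5.02) and OAS1 (-2.19) lower, and NF-kB targets 9 of 29 higher and 14 lower (adjusted p = 0.380), with VCAM1 (-6.32) and TNFAIP2 (-1.40) lower. IFITM1 shares 32.5% of its exon bases with IFITM2.

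Histone genes had 8 of 16 higher and 2 lower (adjusted p = 0.0852), with H2AC6 at 0.79 and H4C8 at -2.55, and passed without control replicate 3 (adjusted p = 0.0253) and without ARD1 replicate 3 (adjusted p = 0.0490, range over its alternatives 0.0253 to 0.465). Epithelial-mesenchymal transition genes had 9 of 26 higher and 13 lower (adjusted p = 0.340), and fibronectin (FN1) fell from 29439 ± 2573 to 5298 ± 85.5 CPM (-2.47), a share of 2.54% to 2.84% of the counts of a control library and 0.568% to 0.590% of those of an ARD1 library. Nuclear noncoding RNAs had 4 of 6 higher, GAS5 (0.79) and KCNQ1OT1 (0.72) among them, and 2 lower (adjusted p = 0.380). With GC and length trends removed, immediate early genes (adjusted p = 0.000987, range 0.000987 to 0.645) and G2/M genes (adjusted p = 0.0138, range 0.0138 to 0.885) passed, and KCNQ1OT1 did not (adjusted p = 0.0547, range 4.41e-05 to 0.0715).

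Markers of other cell types went in both directions. Endothelial markers had 4 of 6 higher and 2 lower (adjusted p = 0.413), with VWF and the receptor KDR (2.05) higher and CDH5 lower. Fibroblast and stellate markers had 1 of 7 higher and 3 lower (adjusted p = 0.418), including the collagen COL3A1 (-4.80) and LUM (-2.01), and immune markers 1 of 5 higher and 2 lower (adjusted p = 0.444), with ITGAM (-1.20) and PTPRC (1.74 ± 0.622 to 0.0529 ± 0.0460 CPM, -4.91). The sign of the median and of the camera direction differed for interferon genes (0.05, lower), and the mean differed in sign from both for ferroptosis suppressors (median -0.11, mean 0.02, lower) and endothelial markers (median 0.88, mean -0.23, higher). Adjusted over the list alone, the counts were the same in 25 of the 32 lists. In the other 7 they moved by 1 gene. These were the lists of immediate early, G2/M, p53, cholesterol, epithelial-mesenchymal, mitochondrially encoded and oxidative phosphorylation genes. None of the 11 calls held with an estimated correlation, where 4 lists had an unadjusted p under 0.05, and fry, which does not compare a list with other genes, passed all 32.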

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

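The GC and length offsets, library totals, thinning and removal of the 20 most abundant genes were tests chosen after seeing the data. Over 19 alternatives, the count of changed genes lay between 9271 and 11092 against 10223, with leave-one-out counts from 9271 to 10984, and DESeq2 gave 9826. Similar counts were not all the same genes. GC and length offsets kept 8868 of the 10223 calls in edgeR and turned 46 to a call in the other direction, and library totals kept 8613 and turned 0. Requiring an absolute log2 fold change of at least 1 left 3406, by construction. The NAA10 log2 fold change lay between 3.23 and 3.64. With the replicate number as a block (replicate block), 10293 genes changed and no call of a named gene or list changed. No pairing by replicate number was visible in the values. Same-numbered libraries had deviation correlations of 0.0168, -0.0356 and 0.0342, and not every library correlated best with its own number (range over all pairs -0.0688 to 0.05005). Whether the numbers mark a shared day or culture is not given in the labels, and these correlations do not settle it.

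Of 2193 values of 116 other named genes under the alternatives, 2167 kept their direction and their side of the threshold, 13 changed sign, 7 lost the call and 6 gained it. The cause was not tested for any of these or of the list results below, unless stated. All 13 sign changes were in genes that did not pass the main test. With GC and length offsets, without and with the block, AIFM2 came to 0.0770 and 0.0775, FTL to 0.13 and 0.13, and NAA15 to -0.13 and -0.13. With library totals AIFM2 came to 0.15, TFRC to 0.23 and FTL to 0.21, a scaling that moved the median of all genes to 0.30. NAA15 passed as higher with library totals (0.46). With upper-quartile scaling TFRC came to 0.0127. Of these, FTL with the offsets or totals and TFRC with totals passed the threshold. Leaving out 1 library gave ranges of -0.0128 to 0.0979 for GSS (below 0 without control replicate 3), -0.0830 to 0.0274 for TFRC (above 0 without ARD1 replicate 1) and -0.147 to 0.0336 for FTL (above 0 without control replicate 1).

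Of the 32 lists, 11 passed camera and 10 to 12 with a library left out. The leave-one-out adjusted p ranged from 0.0185 to 0.0584 for p53 targets (highest without control replicate 2), 0.0457 to 0.0863 for heat shock (lowest without control replicate 1) and 0.0253 to 0.0986 for histones (0.0253 without control replicate 3, 0.0490 without ARD1 replicate 3). The stricter filter ended the call for hepatocyte genes (0.0613), as did the GC and length offsets (0.226), which gave calls for immediate early genes (0.000987) and G2/M (0.0138). Library totals gave a call for NRF2 targets (0.0454) and ended that for oxidative phosphorylation (0.0696). With an estimated correlation 0 lists passed, and 4 had an unadjusted p under 0.05. The adjusted p was 0.368 for ATF4, hypoxia, Wnt and ribosomal protein genes, 0.140 for DNA replication and cholesterol, 0.363 for p53 and fatty acid, 0.481 for hepatocyte, 0.526 for mitochondrially encoded and 0.541 for oxidative phosphorylation genes. All 32 lists passed fry, which tests a list alone and not against other genes. With 64.6% of all tested genes changed, almost any list could pass such a test, so a pass does not set a list apart. Its adjusted p for the 21 others was 0.0145 for N-terminal acetyltransferases, 0.000872 for poly(A)-binding factors and the unfolded protein response, 0.000199 for glutathione synthesis and NRF2 targets, 0.000103 for the methionine cycle and ferroptosis drivers, 0.000171 for glutathione-using enzymes, 0.00742 for ferroptosis suppressors, 0.000339 for iron handling and interferon, 2.30e-05 for heat shock, 0.00462 for NF-kB, 0.00168 for immediate early, 0.0254 for G2/M, 0.00430 for histones, 0.00827 for epithelial-mesenchymal, 0.0198 for noncoding, 0.00366 for immune, 0.0402 for endothelial and 0.000460 for fibroblast genes.

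Depth limits genes with few counts, such as those at 0 in a group, for which folds are bounds. The pseudocount alternatives give no value for counts and were not run.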

Other observations

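The tests of neighbouring gene pairs, of retained control-like cells and of the ATF4 list membership, and the genes in the next 2 paragraphs, were chosen after the results were seen.

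The genes in this paragraph had at least 100 CPM in the higher group. IGFBP1, a secreted binder of insulin-like growth factors, rose from 13.4 ± 2.17 to 299 ± 10.9 CPM (log2 fold change 4.48, SE 0.104). LCN2, an iron-siderophore binding protein, rose from 10.8 ± 0.930 to 175 ± 12.9 CPM (4.02, SE 0.0950). TXNIP, an inhibitor of thioredoxin, rose from 185 ± 9.46 to 710.1 ± 47.3 CPM (1.94). In the other direction IGFBP5 fell from 880.3 to 28.7 CPM (-4.94, SE 0.0854), the aldehyde dehydrogenase ALDH3A1 from 1552 to 62.8 CPM (-4.63, SE 0.117), the sodium channel subunit SCNN1A from 296 to 14.3 CPM (-4.38, SE 0.101), S100A4 from 2218 to 203 CPM (-3.45), and the imprinted noncoding RNA H19 from 263 to 21.9 CPM (-3.57, SE 0.361).

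Members of the NRF2 list went both ways, with 19 of 34 lower and 12 higher in a list that did not pass camera. TKT (-2.03), PGD (-1.19), TALDO1 (-0.97) and NQO1 (-1.03) were among the lower members and SRXN1 (1.89), SLC7A11 (1.73) and GCLC (1.17) among the higher. In the ATF4 list, WARS1 (1.27), SESN2 (1.72) and ATF3 (2.63) rose, TRIB3 (-0.20) and SHMT2 (-1.28) fell, and the mRNA of ATF4 itself did not pass the test (0.12). MTHFD2 and FAR1 were near the floor in every library, with 2 to 4 counts for MTHFD2 and 5 to 10 for FAR1.

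The first pattern is the breadth of the change, 10223 genes. The count was 10129 with libraries thinned to equal depth and 10197 without the 20 genes with the most counts. Library totals ran from 21857327 to 25011357 and overlapped between the groups, so thinning could hardly lower the count. The 20 most abundant genes of a library held 11.3% to 15.1% of its counts, and TMM scaling already limits their weight. Neither count therefore decides about depth or a few abundant genes as the cause. The 10 splits of 3 against 3 are too few for a share under 0.05. Of these, 1 split, the real one, gave as many, and the highest other gave 0. Of neighbouring pairs of changed genes 40.6% changed in opposite directions (lower 95% limit 39.6% with pairs taken as independent and 38.9% with whole chromosomes resampled), which argues against gains or losses of chromosome segments as the whole cause, since under 10% was set for that. It is below the 49.999% of unrelated directions, so neighbours went the same way more often than that, as segments or a shared GC content would give. Segments as the cause of most changes or of a part cannot be told apart from other causes by the limits set, as both lower limits are short of the 40% set to exclude most and 5.12% of windows of 50 genes were shifted by more than 0.4, short of the 20% set for a main cause (upper percentile of shuffled orders 0.683%, median 0). Of these 15 windows 13 were lower and 1 was still shifted with GC and length trends removed, so the excess largely goes with the GC trend. Suppose cells that kept the control profile, with a like amount of RNA, made up 10% or more of the ARD1 cultures. At least that share of each transcript would then remain. But 58 of 9556 genes with at least 10 CPM in the controls had an upper 95% counting limit under 10% of the control level. Examples were CDH5 (0.200% left), SOST (0.772%) and VCAM1 (1.25%). For 6 genes the limit was under 2%, so by the same reasoning a plasmid effect on them would need nearly all cells to respond. Had CDH5 transcription stopped in every cell at transfection, the 0.200% left would correspond to a half-life of 5.35 hours. That is a point estimate from 5 counts, and the upper counting limit of 0.467% left would allow a longer one. A later stop would need a shorter one. Transcript half-lives were not measured, so this decides nothing about the plasmid. An effect of the plasmid stays open as a hypothesis, beside cultures that differed before transfection, which no label or table here separates from the group. A technical difference that runs with the group is not excluded either. Median log2 fold changes went from 0.27 in the lowest quintile of GC content to -0.37 in the highest. GC and length offsets kept 8868 of the 10223 calls.

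The second pattern is the lower level of ribosomal protein transcripts, with a median of -0.51. A GC or length trend is unlikely to be the whole cause, since the median was -0.53 with those trends removed, although median log2 fold changes of all genes went from 0.27 in the lowest quintile of GC content to -0.37 in the highest. Scaling moved its size, to -0.24 with library totals as the highest of 3 other scalings, and did not bring it to 0. Mitochondrially encoded transcripts followed, at -0.85 and -0.40 under the same settings against -0.67. A biological cause stays open and was not tested.

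The third pattern is the spread of directions among glutathione synthesis and NRF2 genes, where neither list passed camera (adjusted p = 0.380 and 0.0895). A candidate explanation is that ATF4 drives some of the members that rose. The 5 of the 51 tested genes that are also in the ATF4 list (SLC7A11, SLC3A2, CHAC1, CTH and CBS) had a median 2.10 above that of the other 46, but all 5 belong to the glutathione list and 1 to the NRF2 list, so the difference largely restates the pattern and decides nothing about ATF4. It was 1.93 with GC and length trends removed, which argues against those trends as the whole cause of the difference. CBS fell (-1.91), and GCLC, GCLM and SRXN1 rose without being in the ATF4 list, and protein levels and acetylation were not analysed here.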
